A study of Mus musculus with 4 samples.

How the data were processed

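RNA of regulatory T cells (Treg cells, the CD4 T cells that express the transcription factor Foxp3 and restrain immune responses) from mouse spleen was sequenced in 4 libraries. Per the labels, 2 libraries came from mice with intact Kmt2d (WT) and 2 from mice in which a Cre recombinase driven by Foxp3 deletes a loxP-flanked Kmt2d allele (cKO). The extraction protocol in the labels describes bone marrow macrophages of another knockout, which contradicts the tissue, cell type and genotype fields. The groups here follow those fields, and levels of T cell and macrophage transcripts are given with the results. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

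The authors deposited 1 table of whole-number read counts for 20837 genes, 16328 of them listed as protein coding and 4509 as non-coding. The reads were mapped to the genome build mm10, per the submitters' processing notes. The aligner, the counting tool, the gene annotation release, the library kit and the use of strand are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Every gene in the table has at least 1 count over the 4 libraries. Gene coordinates came from the RefSeq annotation of GRCm38.p6, the same assembly as mm10, matched by the gene number in the deposited table for 20303 genes. Of 709 list members written down, 13 were absent from the table, among them the T cell receptor constant segments and 4 immunoglobulin segments.

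Total counts per library ranged from 28442416 to 35560491, so that 1 read corresponds to between 0.0281 and 0.0352 CPM (counts scaled to library size), and a count of 0 allows a level of up to 0.0844 to 0.105 CPM (3 counts). Intervals from counts cover counting error only. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13861. CPM values were scaled by TMM factors. The groups were compared by edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood F-test (glmQLFit, glmQLFTest) and a design of group alone, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F.

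Before the data were examined, 33 gene lists were fixed, 23 for T cell states and pathways and 10 for markers of cell types that a spleen sort or a macrophage culture could hold. Lists with at least 5 members tested (32 of the 33) were compared with all other genes by limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the lists. Genes named in the text were chosen by a rule fixed at the same time: Kmt2d, P2rx7 and Foxp3, then the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM, a symbol that is not a predicted gene, clone or pseudogene name, and both cKO libraries on the same side of both WT libraries, then up to 4 members of each list with the smallest p. Where 5 or fewer members of a list rose, fell or did not pass, some of these are named as well, and such names were chosen after their values were seen. Fisher's exact test compared the share of called genes within 10 Mb of Kmt2d with that among all other tested genes. Windows of 5 and 20 Mb were alternatives.

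The gene test was checked on simulated counts of 2 against 2 libraries, 5 simulations with 200 changed genes each and 13706 to 13742 genes tested. With dispersions drawn from the trend, 62.3% of the 1.5-fold, 81.3% of the 2-fold and 96.2% of the 4-fold changes were called, none with the wrong sign, and 4.66% of calls were false. With dispersions kept per gene these shares were 57.4%, 75.7% and 90.5%, and 9.02% of calls were false, so that the adjusted p can be optimistic. The real comparison called 4380 of 13861 genes, far more than the 200 changed in a simulation. These rates may therefore differ in the real data. In 5 simulations of a list shifted 1.5-fold, camera called it 5 times with the preset correlation and 0 times with an estimated one. The estimated one has little power with 2 libraries per group. Of 155 tests of unshifted lists with the preset correlation, 1 was called. Genes were simulated independently, so this does not check the error for lists whose members move together. In the real libraries the estimated correlation ran from -0.02 (Th2) to 0.96 (erythroid and platelet), with 0.75 for proliferation and 0.48 for neutrophil genes, against the preset 0.01.

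Alternatives set at that time were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a filter of 5 CPM in 2 libraries, thinning to the smallest library, the replicate number as a block, leaving out each library, thresholds of 0.10 and of 2-fold, and for the lists an estimated correlation, fry and a prior count of 0.5. A block of crossed replicate numbers was added after seeing the data. Spearman correlations of log2 CPM were 0.996 within either group and 0.981 to 0.986 between groups. The chi-square per degree of freedom between the 2 libraries of a group was 9.59 for WT and 8.88 for cKO, so no library is a copy of another within sampling noise. No library was left out. Random gene lists and term enrichment used Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.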

Results

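The expression data cover 4 libraries of splenic Treg cells, 2 labelled WT and 2 labelled cKO. Total counts were 35560491 and 30737750 in the WT libraries and 28442416 and 34225385 in the cKO libraries. Between 17784 and 18165 genes had at least 1 count in a library. Mitochondrial genes took 2.45% to 2.56% of the counts. Values are TMM-scaled CPM, as mean ± SD over n = 2 libraries of a group.

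The comparison asks how the transcriptome of Treg cells differs when the histone H3 lysine 4 methyltransferase gene Kmt2d is deleted in Foxp3-expressing cells, with the ATP-gated channel P2X7, encoded by P2rx7, named in the study's title. Transcripts of the Kmt2d gene (gene number 381022, mm10 chromosome 15, 98831669 to 98874077) were not lower in the libraries labelled cKO. Kmt2d measured 721 and 704 CPM in the WT libraries and 836 and 793 CPM in the cKO libraries, a log2 fold change of 0.19 (SE 0.05, edgeR quasi-likelihood adjusted p = 0.0375, both cKO libraries above both WT libraries). This rise is small and its call ends with RLE scaling (edgeR adjusted p = 0.0556). It also ends without WT 1 (edgeR adjusted p = 0.109), WT 2 (0.148), cKO 1 (0.237) or cKO 2 (0.0951). A count over the whole gene can include exons outside the deleted part, so it neither checks nor contradicts the labels, and the directions below are those between libraries labelled cKO and WT.

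P2rx7 and Foxp3 were both lower in the libraries labelled cKO. P2rx7 (gene number 18439, chromosome 5, 122643927 to 122692336) fell from 192 ± 9.92 to 93.7 ± 3.13 CPM, a log2 fold change of -1.03 (SE 0.06, edgeR quasi-likelihood adjusted p = 0.00205). Foxp3 (gene number 20371, chromosome X, 7579676 to 7595243) fell from 264 ± 19.4 to 175 ± 7.34 CPM, a log2 fold change of -0.59 (SE 0.07, edgeR quasi-likelihood adjusted p = 0.00493). Both cKO libraries lay below both WT libraries for either gene, and both calls held in each alternative run. The annotated Foxp3 gene overlaps Flicr on the same strand (log2 fold change 0.36, SE 0.19, not passing) and Ccdc22 on the opposite strand, which rose by 0.74 on the log2 scale (SE 0.07, edgeR adjusted p = 0.00363). These neighbours were looked up after the values were seen.

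**Figure D1:**
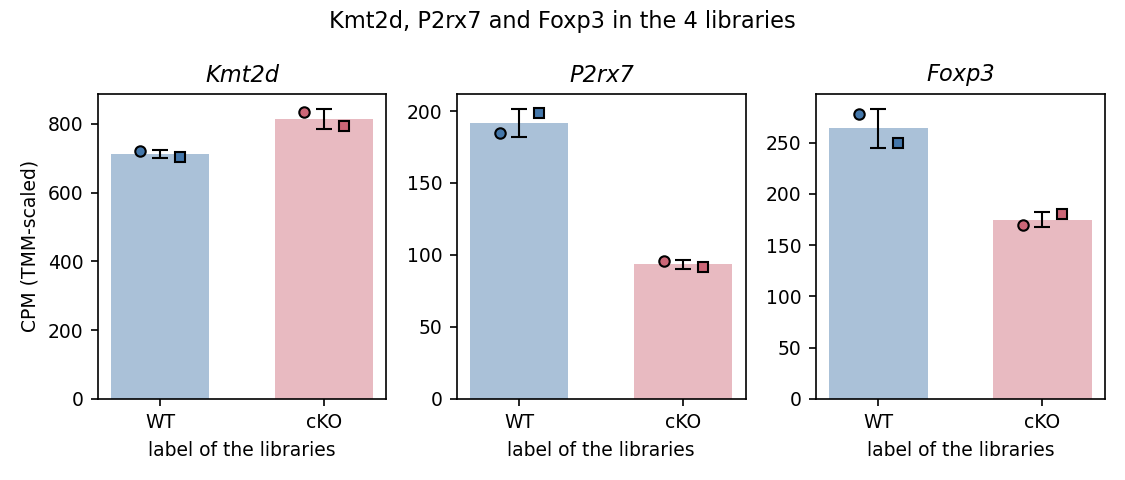
Levels of Kmt2d, P2rx7 and Foxp3 in TMM-scaled CPM, with each library as a point (circle, replicate 1; square, replicate 2), the group mean as a bar and the SD (n = 2) as an error line. Kmt2d measured 713 CPM in WT and 814 CPM in cKO, P2rx7 192 and 93.7 CPM, and Foxp3 264 and 175 CPM.

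Across the transcriptome, 4380 of 13861 tested genes differed between the groups, 2292 of them higher and 2088 lower in the libraries labelled cKO (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 1124 changed at least 2-fold, 689 upwards and 435 downwards, and the median log2 fold change of all tested genes was 0.0003. Which direction holds more genes depends on the scaling: RLE gave 2133 higher and 2212 lower, and upper-quartile scaling 2546 and 1877. DESeq2, which also differs in its test and filter, gave 1301 and 1575. With TMM scaling kept, the balance also turned to more lower genes without WT 1 and without cKO 2. The count rests on few libraries: it was 1869 without WT 1, 2747 without WT 2, 2173 without cKO 1 and 2466 without cKO 2, while DESeq2 called 2876. No gene called both in the full comparison and in any of these 5 changed sign, which says little because the fits share libraries.

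The 10 largest rises within the limits of the naming rule, among them a mean of at least 1 CPM, include 5 genes known from basophils or neutrophils. Mcpt8 and Prss34, proteases of basophils, rose by 3.74 and 4.24 on the log2 scale (SE 0.52 and 0.68), and the neutrophil collagenase Mmp8 and the chitinase-like gene Chil1 by 3.48 (SE 0.42) and 3.75 (SE 0.59). Ly6g, a surface marker of neutrophils, had 3 counts over the WT libraries and 176 over the cKO libraries, a ratio of 62.1 with an exact 95% counting interval of 20.9 to 304. Pard3b, a cell polarity gene, reached 3.78 ± 0.19 CPM from 0.205 ± 0.127 CPM (log2 fold change 4.21), the neurobeachin gene Nbea rose by 3.87, the coagulation factor gene F5 by 3.77 and Rab44 by 3.41. Scart2, a scavenger receptor gene known from γδ T cells, rose from 1.39 ± 0.453 to 17.1 ± 2.51 CPM, a log2 fold change of 3.63 (SE 0.23). All 10 had edgeR quasi-likelihood adjusted p between 0.00224 and 0.00839, and all kept their call in each alternative that tested them. Their sizes rest on few libraries. Without WT 1 and without WT 2 the log2 fold changes were 3.36 and 6.24 for Prss34 (3.62 without cKO 2), 3.00 and 5.10 for Mcpt8, 3.00 and 5.15 for Chil1 and 2.83 and 4.57 for Mmp8. In the same order they were 3.17 and 4.66 for F5 and 2.65 and 4.91 for Rab44, and Pard3b had 4.99 without WT 2 and Ly6g 4.71 without cKO 2.

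Within the same rule the largest fall was in Noxa1, which encodes an activator of NADPH oxidase. It had 274 counts over the WT libraries and 1 count over the cKO libraries. The ratio of WT over cKO was 259, with an exact 95% counting interval of 46.1 to 10267. Sp6, a zinc finger transcription factor gene, fell from 23.7 ± 1.30 to 1.12 ± 0.510 CPM, a log2 fold change of -4.37 (SE 0.23). Osgin1, a gene induced by oxidative stress, fell from 30.1 ± 2.10 to 2.75 ± 0.579 CPM (log2 fold change -3.44, SE 0.15). The carboxylesterase gene Ces2c had a log2 fold change of -3.09, Fhip1a of -3.03, the laminin receptor gene Bcam of -3.11, the exchanger gene Slc24a3 of -3.09, Tmem63c of -4.27 and Ypel4 of -3.45. These 10 falls had edgeR quasi-likelihood adjusted p between 0.00159 and 0.00595. The 1 count of Noxa1 lies in cKO 1, so that without this library its fold change has no measured size, and without cKO 2 it was -6.78 on the log2 scale. Without cKO 2 the log2 fold changes were -4.96 for Sp6, -4.08 for Ces2c, -4.14 for Slc24a3, -4.92 for Tmem63c and -4.85 for Ypel4 (-2.84 without cKO 1). Entpd4b (log2 fold change -3.44) is near-identical to Entpd4, and the authors' counting could have split reads between the copies, so its value is uncertain. Ly6g, Mcpt8, Ces2c and Prss34 also belong to multigene families. On the opposite strand Noxa1 overlaps Entpd8, Sp6 overlaps Gm11532 and Entpd4b overlaps Gm27177. Among the rises, Nbea overlaps Mab21l1 and F5 overlaps Gm16548 in the same way. Their counts could include reads of these genes if strand was not used. These overlaps were looked up after the values were seen.

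Genes of Treg identity were mostly lower. Of 25 such genes tested, 18 fell, 2 rose and 5 did not pass, and adjusted over the list alone 19 fell and 3 rose. Nrp1, a surface receptor of thymus-derived Treg cells, fell from 355 ± 6.05 to 136 ± 15.2 CPM (log2 fold change -1.39, SE 0.08). Ebi3, a subunit of interleukin 35, fell by 1.74 on the log2 scale and the matrix protein gene Ecm1 by 0.74. Socs2, a suppressor of cytokine signalling, rose by 1.56 and Il2ra, which encodes the interleukin 2 receptor alpha chain, by 0.38 (SE 0.06). The 5 that did not pass were Itgae (log2 fold change -0.25), Gpr83 (0.23), Lrrc32 (-0.22), Ctla4 (-0.18) and Ikzf2 (-0.08). The list median was -0.54 (limma camera adjusted p = 2.6e-05; adjusted p = 0.693 with an estimated correlation). Pan T cell transcripts were lower in these libraries as well, with a list median of -0.32.

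Effector Treg genes moved both ways. Of 29 tested, 9 rose, 13 fell and 7 did not pass, and adjusted over the list alone 9 rose and 15 fell (median -0.16, camera adjusted p = 0.165). Il1rl1, the receptor of the alarmin interleukin 33, fell from 35.8 ± 1.83 to 7.58 ± 1.04 CPM, a log2 fold change of -2.23 (SE 0.11), while the chemokine receptor gene Ccr2 rose by 1.22 (SE 0.13) and the galectin gene Lgals3 by 0.80 (SE 0.08). Among 20 genes of naive or resting T cells, 5 rose, 7 fell and 8 did not pass, with the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.442). Igfbp4 rose by 0.85 and the survival gene Bcl2 by 0.59, whereas Ly6c1 fell by 1.30 and the actin crosslinker gene Actn1 by 0.47.

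In the Th1 and cytotoxic list 11 of 20 genes rose, 5 fell and 4 did not pass, the same counts adjusted over the list alone (median 0.51, camera adjusted p = 0.0694, and 0.0345 without WT 2). The granzyme gene Gzma rose by 1.59 (SE 0.17), Il12rb2 by 1.47 (SE 0.15) and Il18rap by 0.90 (SE 0.10). Among those that fell were the interferon gamma receptor gene Ifngr1 (-0.66), Fasl (-0.59) and Cxcr3 (-0.48). Markers of CD8 T cells and NK cells, 4 of them shared with this list, were also higher in these libraries, with a list median of 0.60. The Th1 regulator gene Tbx21 measured 21.7 ± 0.849 CPM in WT and 21.6 ± 1.43 CPM in cKO and did not pass. In the Th2 list 7 of 12 genes fell, 0 rose and 5 did not pass, again the same adjusted over the list alone (camera adjusted p = 0.00305; adjusted p = 0.693 with an estimated correlation). They include Il1rl1, the anti-inflammatory cytokine gene Il10, which fell from 33.7 ± 2.63 to 11.8 ± 3.86 CPM (log2 fold change -1.51, SE 0.21), Ccr8 (-1.34, SE 0.17) and Ccr4 (-0.42, SE 0.06). These 4 are also in the Treg lists. In the Th17 list 2 of 13 genes rose, 6 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0558, and 0.0387 without cKO 2). Rora fell by 0.95, Il21r by 0.57 and the chemokine receptor gene Ccr6 by 0.50. In the follicular list 7 of 16 genes fell, 0 rose and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.693 with an estimated correlation). Tox2 fell by 1.59 (SE 0.11), Angptl2 by 1.36, the checkpoint receptor gene Pdcd1 by 0.59 and the follicular regulator gene Bcl6 by 0.52. The follicular median was -0.18 and the Th2 median -0.53, beside a pan T cell median of -0.32 in the same libraries.

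Of 19 tested genes in the list of purinergic receptors and nucleotide enzymes, 8 fell, P2rx7 among them, 1 rose and 10 did not pass. Adjusted over the list alone 9 fell and 2 rose (median -0.33, camera adjusted p = 0.0141, and adjusted p = 0.693 with an estimated correlation). Pan T cell transcripts were lower by a list median of -0.32 in the same libraries. Adora2a, an adenosine receptor gene, fell from 109 ± 24.5 to 30.7 ± 5.33 CPM, a log2 fold change of -1.82 (SE 0.18). Adk, which phosphorylates adenosine, fell by 0.87 (SE 0.07) and Entpd1, the ectoenzyme CD39 that degrades ATP, by 0.76 (SE 0.07). The 1 that rose, P2ry6 (0.70), loses its call without WT 1 (edgeR adjusted p = 0.102), WT 2 (0.162), cKO 1 (0.195) or cKO 2 (0.0942). The list call ended without cKO 1 (camera adjusted p = 0.110) and without cKO 2 (camera adjusted p = 0.0800).

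Genes of inflammasomes and pyroptosis went both ways, with 5 of 20 higher, 5 lower and 10 not passing (6 lower adjusted over the list alone, 5 higher; median -0.15, camera adjusted p = 0.530). Txnip rose by 0.78 (SE 0.08) and Card9 by 1.37 (SE 0.20), while Naip5 fell by 1.29 (SE 0.14) and the DNA sensor gene Aim2 by 0.35. Of 30 apoptosis genes, 8 rose, 4 fell and 18 did not pass, the same adjusted over the list alone (median 0.04, camera adjusted p = 0.442). The proapoptotic gene Bbc3 (PUMA) rose by 0.86 (SE 0.06) and the antiapoptotic gene Bcl2 by 0.59 (SE 0.05), and the death receptor gene Tnfrsf10b fell by 1.43 (SE 0.18).

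Transcripts induced by T cell receptor signalling and immediate early genes were lower as a group. Of 29 tested, 16 fell, 4 rose and 9 did not pass, and adjusted over the list alone 16 fell and 5 rose (median -0.32, camera adjusted p = 0.0136; adjusted p = 0.784 with an estimated correlation). Nr4a3, an orphan nuclear receptor gene, fell by 1.57 on the log2 scale (SE 0.19), the AP-1 gene Fosl2 by 1.44 (SE 0.16) and Nfkbid by 0.47 (SE 0.06), whereas Myc rose by 0.68 (SE 0.08). Pan T cell transcripts were lower by a similar list median, -0.32, in the same libraries, beside this list and the next 2. Without cKO 1 this list's call ended (camera adjusted p = 0.0516). In the interleukin 2 and STAT5 list 13 of 22 genes fell, 4 rose and 5 did not pass, and adjusted over the list alone 13 fell and 5 rose (median -0.31, camera adjusted p = 0.0227; adjusted p = 0.693 with an estimated correlation). The prostaglandin receptor gene Ptger2 fell by 1.18 (SE 0.11), and the 4 that rose were Socs2, Bcl2, Myc and Il2ra. In the TGF-beta list 13 of 21 genes fell, 0 rose and 8 did not pass, with 14 lower adjusted over the list alone (median -0.29, camera adjusted p = 6.05e-04; adjusted p = 0.693 with an estimated correlation). The integrin gene Itgb8, whose product activates latent TGF-beta, fell by 0.77 (SE 0.07), Tgif1 by 0.98 (SE 0.12), the signal transducer gene Smad3 by 0.57 (SE 0.07) and Skil by 0.65 (SE 0.08).

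Cell cycle genes were higher in the libraries labelled cKO. Of 32 proliferation genes, 31 rose and 1, the replication clamp gene Pcna (log2 fold change -0.05, SE 0.05), did not pass, with the same counts adjusted over the list alone. Mki67, a marker of cycling cells, rose from 182 ± 21.3 to 355 ± 27.6 CPM (log2 fold change 0.96, SE 0.10), and the centromere gene Cenpf, the cyclin gene Ccna2 and the kinesin gene Kif11 by 1.01, 0.93 and 1.00. The list median was 0.83 (camera adjusted p = 2.66e-10; adjusted p = 0.693 with an estimated correlation). Transcripts of neutrophils were also higher in these libraries, with a list median of 2.88.

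In the oxidative phosphorylation list 7 of 40 genes rose, 0 fell and 33 did not pass (6 higher adjusted over the list alone; median 0.10, camera adjusted p = 0.00846; adjusted p = 0.784 with an estimated correlation). The ATP synthase gene Atp5b rose by 0.26, a call lost without WT 1 (edgeR adjusted p = 0.0718), cKO 1 (0.0594) or cKO 2 (0.0770), and Atp5c1 by 0.27, lost without WT 1 (0.0761), cKO 1 (0.0585) or cKO 2 (0.0701). The list call ended without WT 1 (camera adjusted p = 0.0973) and without cKO 2 (camera adjusted p = 0.0586). Of 41 ribosomal protein genes, 9 rose, 2 fell and 30 did not pass, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.00902; adjusted p = 0.821 with an estimated correlation). With RLE scaling 5 and with upper-quartile scaling 16 of them rose. Rps19 rose by 0.43 (SE 0.06), and the list call ended without WT 2 (camera adjusted p = 0.0881) and without cKO 2 (camera adjusted p = 0.194). Of 22 glycolysis genes, 7 rose, 4 fell and 11 did not pass (8 and 6 adjusted over the list alone; camera adjusted p = 0.859). Their median of 0.0006 turns to -0.02 with RLE scaling and their mean is -0.01. Hif1a fell by 0.45 and the glucose transporter gene Slc2a1 by 0.45, while Pgam1 rose by 0.49 and Pgk1 by 0.36. In cholesterol synthesis 3 of 25 genes fell, 0 rose and 22 did not pass (0 lower adjusted over the list alone; camera adjusted p = 0.442, and 0.0387 without cKO 2). The desaturase gene Scd2 fell by 0.37, a call lost without WT 2 (edgeR adjusted p = 0.0649) or cKO 2 (0.0673), and Insig1 had a log2 fold change of -0.49 (SE 0.18, not passing). None of the 13 mitochondrial genome transcripts passed in the edgeR test with TMM scaling, with or without adjustment over the list alone (median -0.03, mean 0.02, camera adjusted p = 0.794). With upper-quartile scaling the median was 0.002 and 1 transcript was called higher, whereas DESeq2 called 1 lower. Of 14 heat shock genes, 4 fell, 1 rose and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.546). Bag3 fell by 0.77 and Dnaja1 by 0.37, the list median was 0.02 and its mean -0.04, and the median turns to -0.002 with RLE scaling.

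Among 37 interferon response genes, 13 rose, 5 fell and 19 did not pass, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.0686, but 0.0350 without WT 1 and 0.0281 without cKO 1). The guanylate binding protein genes Gbp2 and Gbp3 rose by 0.46 and 0.41 and the GTPase gene Iigp1 by 0.51, whereas the chemokine gene Cxcl10 fell by 0.94 (SE 0.12). Of 29 genes for histone methylation and demethylation, Kmt2d included, 6 rose, 5 fell and 18 did not pass, the same adjusted over the list alone (median -0.07, camera adjusted p = 0.488). The demethylase gene Kdm6b fell from 365 ± 48.3 to 185 ± 23.2 CPM (log2 fold change -0.98, SE 0.12) and Ezh1 by 0.31, while Ezh2 rose by 0.52 (SE 0.07) and Pagr1a, a subunit gene of the complex that holds KMT2D, by 0.57 (SE 0.07). Of 28 homing receptor and integrin genes, 6 rose, 10 fell and 12 did not pass, and adjusted over the list alone 7 rose and 12 fell (median -0.15, camera adjusted p = 0.340). Besides Ccr2, Ccr1 rose by 1.41 (SE 0.15) and Gpr15, a gut homing receptor gene, by 0.99 (SE 0.11).

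**Figure D2:**
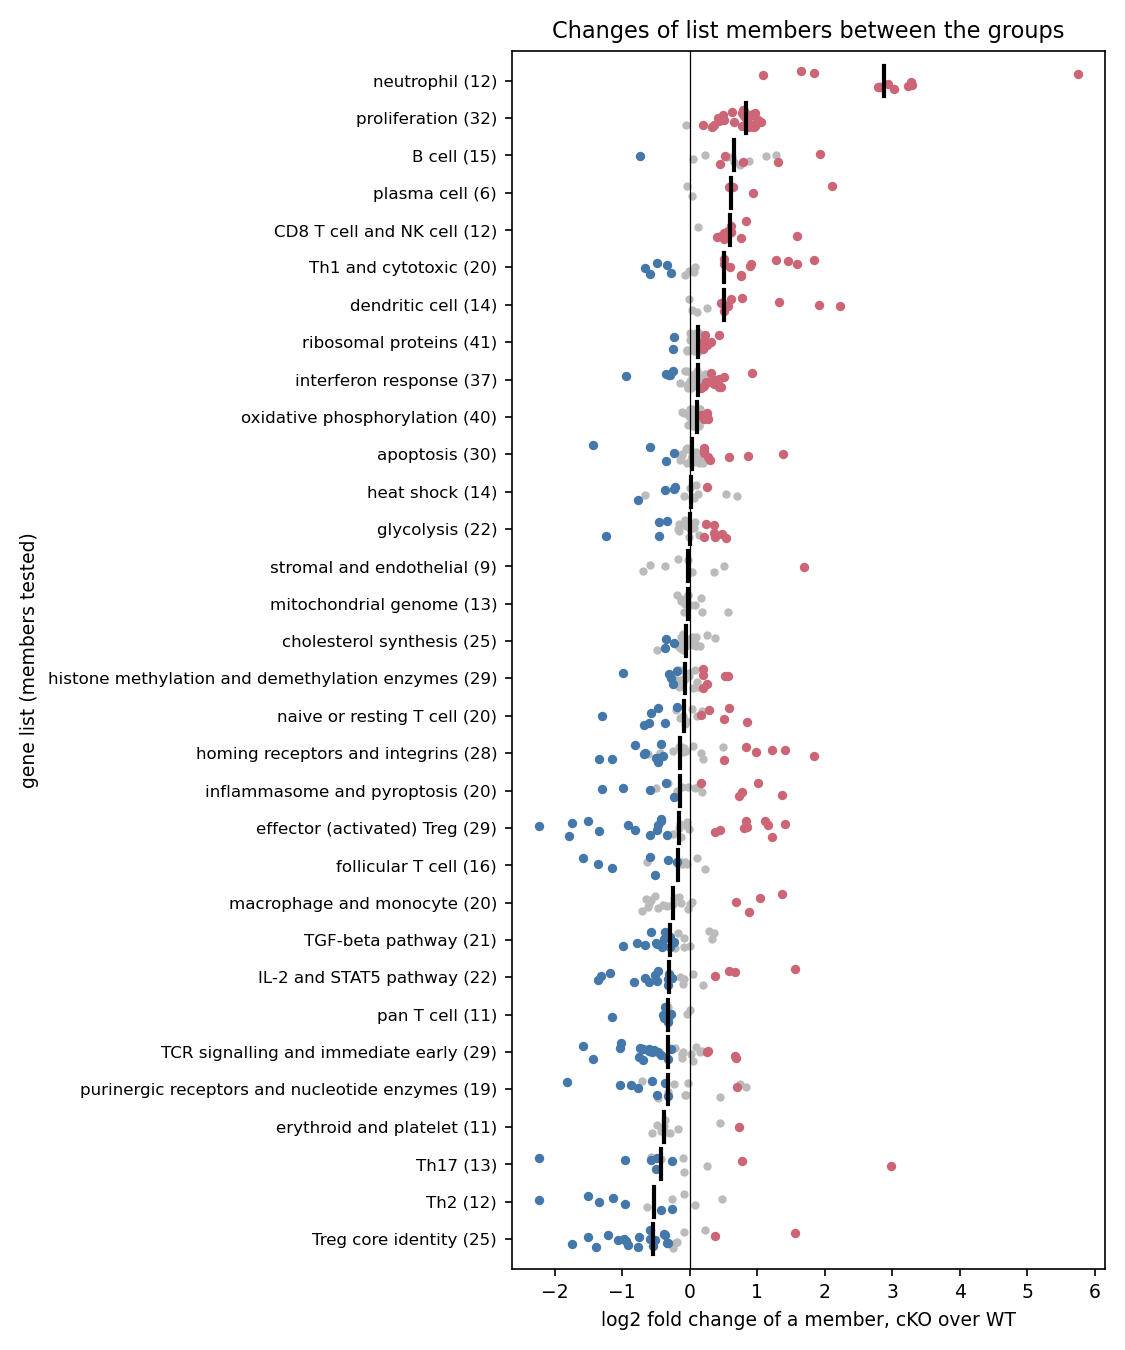
Log2 fold change (cKO over WT) of each tested member of the 32 lists with at least 5 members; red and blue points passed the edgeR test upwards and downwards, grey points did not pass, and black bars are list medians. The neutrophil median lies at 2.88 and the proliferation median at 0.83, and the Treg core median at -0.54.

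Markers of other cell types were measured beside the T cell genes, because a sort can hold other cells and the labels' protocol names macrophages. T cell transcripts were abundant in every library. The median of 11 pan T cell genes was 546 CPM in WT and 379 CPM in cKO, against 39.1 and 31.4 CPM for 20 macrophage and monocyte genes. Of the pan T cell genes 8 fell, 0 rose and 3 did not pass, the same adjusted over the list alone (median -0.32, camera adjusted p = 0.00147; adjusted p = 0.693 with an estimated correlation). Thy1 fell from 583 ± 28.5 to 264 ± 23.3 CPM (log2 fold change -1.14, SE 0.08), Lck by 0.36 and Cd2 by 0.35, and the 3 that did not pass were Cd28 (-0.32), Cd3e (-0.04) and Cd5 (0.01).

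All 12 neutrophil genes rose, also when adjusted over the list alone, with a median log2 fold change of 2.88 (camera adjusted p = 5.48e-05; adjusted p = 0.693 with an estimated correlation). The chemokine receptor gene Cxcr2 rose by 1.84 (SE 0.14), the growth factor receptor gene Csf3r by 1.09 (SE 0.08) and Retnlg by 2.81 (SE 0.33; 3.52 without WT 2). These transcripts also differed within groups. S100a9, an abundant granulocyte transcript named here after its values were seen, measured 18.7 and 51.6 CPM in the WT libraries and 155 and 326 CPM in the cKO libraries, a log2 fold change of 2.79 (3.69 without WT 2, 2.15 without cKO 2). Dendritic cell genes rose in 9 of 14 cases, with 0 lower and 5 not passing (10 higher adjusted over the list alone; median 0.51, camera adjusted p = 3.08e-04; adjusted p = 0.693 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, rose by 1.91 (SE 0.11), Itgax by 0.78 and the MHC class II genes H2-Aa and H2-Ab1 by 0.61 and 0.47. Of 12 genes of CD8 T cells and NK cells, 4 of which are also in the Th1 and cytotoxic list, 11 rose and 1, Klrb1c (log2 fold change 0.13), did not pass, the same adjusted over the list alone (median 0.60, camera adjusted p = 2.41e-04; adjusted p = 0.693 with an estimated correlation). Klrd1 rose by 0.62, Eomes by 0.76 and the perforin gene Prf1 by 0.51.

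The remaining marker lists did not pass in the camera test with the preset correlation, the filter, all 4 libraries and a design of group alone. Of 15 B cell genes, 5 rose, 1 fell and 9 did not pass, with 6 higher adjusted over the list alone and 2 with RLE scaling (median 0.65, camera adjusted p = 0.0608), and the complement receptor gene Cr2 rose by 1.31 (SE 0.27). The 1 that fell was Cd72 (-0.74), which did not pass without WT 2 (edgeR adjusted p = 0.0525). The B cell list passed without WT 2 (camera adjusted p = 0.0412) and without cKO 1 (1.2e-04), and the plasma cell list without WT 2 (0.00633). Of 6 plasma cell genes, 4 rose, among them Jchain (0.59) and Mzb1 (0.94), and 2 did not pass, the same adjusted over the list alone (median 0.61, camera adjusted p = 0.0703). Among macrophage and monocyte genes 4 rose and 16 did not pass, the same adjusted over the list alone (median -0.24, camera adjusted p = 0.767). DESeq2 called 4 of them higher and 4 lower. Those that rose were Lyz2 (1.04, SE 0.07), Itgam (1.37, SE 0.11), Ms4a6c (0.69) and Cd300e (0.88), and Lyz2 and Itgam are also expressed by neutrophils. The 11 erythroid and platelet genes included 1 that rose and 10 that did not pass, the same adjusted over the list alone (median -0.38, camera adjusted p = 0.859). The 1 that rose, Itga2b (0.74), did not pass without WT 1 (edgeR adjusted p = 0.0735), WT 2 (0.0966), cKO 1 (0.0928) or cKO 2 (0.101). Of 9 stromal and endothelial genes, Kdr rose (1.69, but edgeR adjusted p = 0.0538 without WT 1) and 8 did not pass, the same adjusted over the list alone (median -0.02, which is 0.004 with upper-quartile scaling, mean 0.09, camera adjusted p = 0.767). The 4 sex-specific transcripts tested did not pass, adjusted over the list alone or over all genes. Y-linked Ddx3y had a log2 fold change of -0.01 (SE 0.07).

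**Figure D3:**
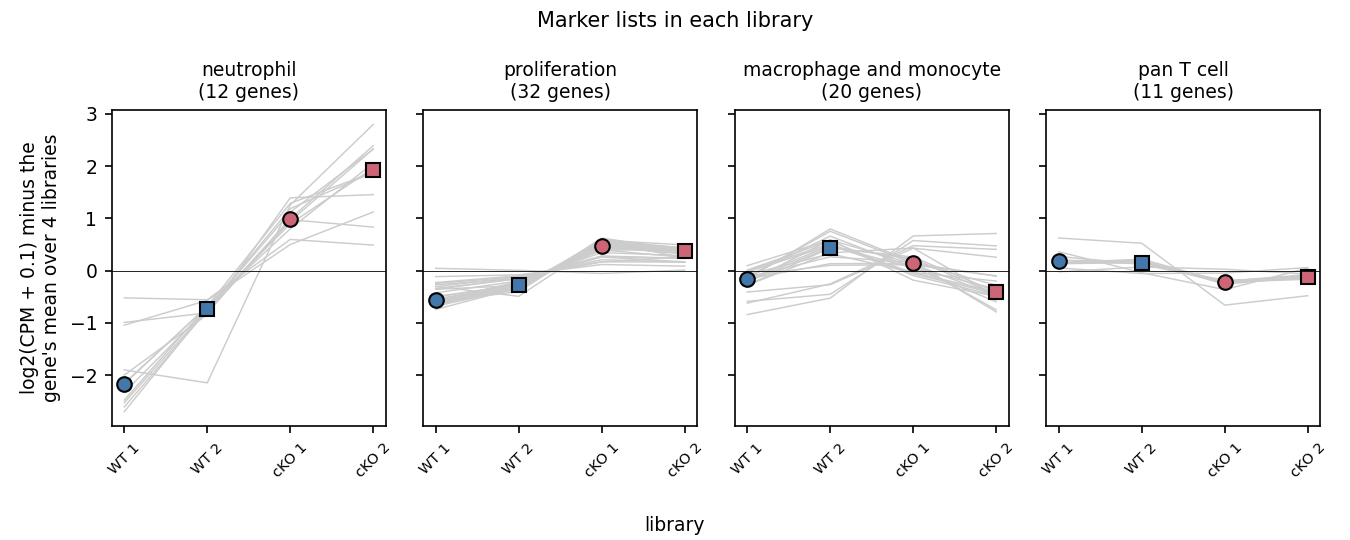
Level of each member of 4 lists per library, as log2(CPM + 0.1) minus the gene's mean over the 4 libraries (grey lines), with the list median as a point coloured by label (blue, WT; red, cKO). The neutrophil medians are -2.16 and -0.73 in the WT libraries and 0.98 and 1.92 in the cKO libraries, while the proliferation medians are -0.57, -0.28, 0.47 and 0.37 in the same order.

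A floxed allele can carry flanking sequence of another strain, so the genes around Kmt2d were compared with the rest. Within 10 Mb of Kmt2d, 52 of 152 tested genes were called (34.2%), against 31.8% of 13550 other genes with coordinates. The odds ratio was 1.12 with a 95% interval of 0.782 to 1.58 (Fisher's exact test, 2-sided, p = 0.540). Within 5 Mb 36.1% of 122 genes were called (odds ratio 1.21, Fisher's exact test, p = 0.329). Within 20 Mb it was 36.9% of 268 (odds ratio 1.26, 95% interval 0.973 to 1.63, Fisher's exact test, p = 0.0735). Of these 268 genes, 36 were higher and 63 lower. An excess near Kmt2d of a size that these intervals allow is not excluded.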

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

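All alternatives were set before the data were examined except the crossed block. The number of genes changed, 4380 in the full comparison, stayed within 1.5 times under RLE and upper-quartile scaling, limma-voom, no filter, the 5 CPM filter, thinning and a threshold of 0.10. DESeq2 called 2876 genes, 1301 of them higher, and left 6464 genes without an adjusted p; the cause was not tested. Asking for at least 2-fold change left 1124 genes, 689 higher and 435 lower, by construction. Leaving out 1 library at a time gave 1869 to 2747 genes, 886 to 1375 higher and 983 to 1372 lower, with fewer samples and the lone library assumed to vary like the other group. The labels do not say that equal replicate numbers share a mouse or day, and over all tested genes the deviations of same-numbered libraries correlated at -0.32. With the replicate block 2292 genes were called, 1151 higher and 1141 lower. With crossed numbers, chosen after seeing the data, 6713 were called, 3520 higher and 3193 lower. No gene called in the full comparison and in one of these fits changed sign, which says little because the fits share libraries. The Kmt2d log2 fold change of 0.19 no longer passed with RLE scaling (0.17), with the replicate block (0.19) or without any 1 library (0.15 to 0.23). P2rx7 (-1.09 to -0.98) and Foxp3 (-0.67 to -0.52) passed in each alternative. Of 32 list tests, 14 passed with the preset correlation and 13 to 18 in the scaling, filter, prior count, block and leave-one-out fits, but 0 with limma's estimated correlation, where 2 libraries per group leave little power, and 0 with fry. Lists past the threshold only in such a fit were Th1 and cytotoxic (camera adjusted p = 0.0378 with no filter, 0.0467 with the replicate block), Th17 (0.0476 with no filter, 0.0493 with a prior count of 0.5, 0.0312 with the block), B cell (0.0314 with no filter, 0.00230 with the block) and plasma cell (0.0416 with no filter, 0.0312 with the block), besides those with a library left out given above. DESeq2 called fewer members higher in the apoptosis (4), histone enzyme (3), inflammasome (3) and oxidative phosphorylation (3) lists, where edgeR called 8, 6, 5 and 7; the cause was not tested. For 145 named genes, 1756 of 1863 alternative values kept direction and side of the threshold, 85 lost and 14 gained the call, and 8 changed sign, all in genes that had not passed: Ahsp (-1.24 to 0.432 with 1 library left out), Ppbp (-0.148 to 1.08), Hbb-bs (-1.24 to 0.511), Eif2s3y (-0.163 to 0.215) and Ddx3y (-0.105 to 0.0811, and 0.0136 with upper-quartile scaling), the cause not tested. With 1 count worth 0.0281 to 0.0352 CPM, genes under 1 CPM rest on few reads.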

Other observations

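All tests in this part were chosen after the results they bear on were seen. In the terms that the deposited table gives for its genes (10 to 300 tested members, one-sided Fisher's exact test against all annotated tested genes, Benjamini-Hochberg adjusted over the terms of a source), some T cell signalling terms were over-represented among the lower genes, and the terms given here are examples picked by name. Of 99 tested genes of the KEGG pathway for Th17 cell differentiation, 45 fell (45.5%; adjusted p = 1.51e-09), as did 45 of 111 genes of T cell receptor signalling (adjusted p = 8.34e-08) and 40 of 106 genes of JAK-STAT signalling (adjusted p = 2.86e-06). In the Reactome terms, 10 of 13 genes of PD-1 signalling fell (adjusted p = 2.26e-04). Of all annotated tested genes, 16.2% fell in the KEGG source and 15.5% in the Reactome source. Among the higher genes, terms of cell division, defence, MHC class II and T cells passed. In the GO source 17.1% of all annotated tested genes rose. Of 30 tested genes of the GO term mitotic sister chromatid segregation, 22 rose (Fisher's exact test, adjusted p = 2.84e-08). So did 24 of 53 genes of neutrophil chemotaxis (adjusted p = 3.28e-04) and 24 of 54 genes of the cellular response to interferon-beta (adjusted p = 4.43e-04). The MHC class II protein complex had 9 of 11 genes higher (adjusted p = 6.6e-04). Positive regulation of T cell activation had 17 of 35 (adjusted p = 0.00172), and its overlap with MHC class II genes was not examined. Genes of one term are not independent, so these p-values are too small.

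Some transcripts known from basophils and mast cells, picked by their values, were also higher in both libraries labelled cKO. No list of such genes was fixed, so these picks do not show how such genes moved as a group. Fcer1a, the alpha chain of the high-affinity IgE receptor, had a log2 fold change of 4.57 (SE 0.52), its beta chain gene Ms4a2 3.57 (SE 0.61), the carboxypeptidase gene Cpa3 3.41 (SE 0.72) and the histidine decarboxylase gene Hdc 2.16 (SE 0.47), all past the edgeR threshold. Without WT 1 the last 3 do not pass (edgeR adjusted p = 0.0554, 0.0869 and 0.0627). The log2 fold changes were 2.92 without WT 1, 4.62 without WT 2 and 2.97 without cKO 2 for Ms4a2, 2.73, 4.58 and 2.47 for Cpa3, and 2.99 without WT 2 for Hdc. Igsf23 fell from 26.9 ± 1.20 to 5.85 ± 0.293 CPM and the synaptic gene Prrt2 rose from 13.4 ± 0.36 to 40.6 ± 0.667 CPM; these 2 had the smallest p-values of all genes (edgeR quasi-likelihood adjusted p = 0.00159). Within 1 Mb of P2rx7, 13 of 36 other tested genes were lower (36.1%), among them Orai1 (-0.86) and Kdm2b (-0.57), which lies above 96.9% of the same shares around 1045 other lowered genes. Within 2 Mb of P2rx7, 43.4% of 83 tested genes were called in either direction (Fisher's exact test, p = 0.0325), and within 5 Mb 43.5% of 108 (p = 0.0123). Within 10 Mb the share was 38.8% of 201, against 31.7% of the others (Fisher's exact test, p = 0.0328), and within 20 Mb 34.9% of 418 (p = 0.166).

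Of the lists fixed here, the neutrophil list had the largest median log2 fold change, 2.88. A lower share of Treg cells that raises every other cell type alike is argued against. The neutrophil median lay above the macrophage and monocyte median by 3.12 on the log2 scale (2.06 to 4.42 over the 4 pairs of a cKO and a WT library). A lower share that raises only some cell types is not addressed by this. The B cell (0.65), plasma cell (0.61), CD8 T cell and NK cell (0.60) and dendritic cell (0.51) medians were higher. The macrophage and monocyte (-0.24), erythroid and platelet (-0.38) and stromal and endothelial (-0.02) medians were not. Granulocyte-lineage cells or their RNA in varying amount in the sorted samples could be a source, and cannot be told apart from other causes here. The neutrophil list had a median log2 ratio of 0.88 between cKO 2 and cKO 1 and of 1.48 between WT 2 and WT 1, with 10 of 12 members above 0 and 2 below in each pair, but 5 of 7 other lists also left the range of 10000 expression-matched random lists in both pairs, so this does not single out such cells. Whether Kmt2d deletion in Treg cells raises granulocyte numbers in the spleen, or such genes in the Treg cells themselves, was not tested and stays open.

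The rise of proliferation genes could come from the same granulocyte-lineage cells, and whether these are the whole source cannot be told apart from these 4 libraries. With a baseline plus a share that scales with the neutrophil list, both set by the group means, the proliferation list would have a median log2 ratio of 0.479 between cKO 2 and cKO 1 and of 0.175 between WT 2 and WT 1. It had -0.0889 in the cKO pair, with 29 of 32 members below 0, and 0.261 in the WT pair, so that the pairs point in opposite ways and each is 1 library against 1. Cycling of the Treg cells or of other sorted T cells, as an effect of the genotype, was not tested and remains open.

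The fall of Treg transcripts might reflect Treg RNA diluted by RNA of other cells, conventional T cells included. If the Foxp3 level per Treg cell is unchanged, dilution lowers no Treg transcript further than Foxp3. Yet 8 of 24 other Treg core genes fell further by more than 2 standard errors of the difference, led by Ebi3 and Nrp1. P2rx7 fell further than Foxp3 by -0.44 (SE 0.09). On that condition dilution alone does not account for these. Foxp3 also drives the Cre and its level per cell was not measured, so the condition was not checked. The comparison also takes the Foxp3 count as free of reads from the overlapping gene Ccdc22, which rose. If strand was not used, such reads would make the fall of Foxp3 look too small. For Foxp3 itself, Treg RNA diluted by cells other than T cells is argued against as the whole cause, because 9 of 11 pan T cell genes had a log2 fold change above that of Foxp3 by more than 2 standard errors. Treg RNA diluted by conventional T cells cannot be told apart from a lower Foxp3 level per cell: 9 of the 24 other Treg core genes lay above Foxp3 by more than 2 standard errors, Socs2 and Il2ra among them, which rose, but conventional T cells share several of them and each can be regulated on its own. The labels name sorted Treg cells without the gate, and an effect of the genotype on Foxp3 itself was not tested separately.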
